A study of Mus musculus with 30 samples.

How the data were processed

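RNA of macrophages was sequenced in bulk, 5 libraries for each of 6 groups. Per the submitters' processing notes, reads were trimmed with Trimmomatic, aligned with STAR to the mouse genome GRCm38 and assigned to genes with featureCounts, with no versions given. The deposited count table holds raw read counts of 46603 genes, of which 25626 had at least 1 count in any library. The second deposited table holds FPKM of 13778 genes (29.6% of those in the count table). In that table the values times gene length have the same distribution in each of the 30 columns, as quantile normalisation gives, and the filter that chose its genes is not stated. Replicate numbers in the headers of cultured columns (1, 3, 4, 5 and 6, or 3 to 7 in no-lactate MHC-IIhi) are other than those in the sample labels, so a cultured column could be placed in its group and not with a single sample record.

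Counts were analysed with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 in R 4.3.3. Genes with enough counts for the groups of a fit (filterByExpr) were scaled with TMM and tested with the edgeR quasi-likelihood F test, 2-sided, with Benjamini-Hochberg adjustment over the genes tested, and a gene passed at an adjusted p under 0.05. The fresh subsets were fitted on the 10 fresh libraries, the 4 comparisons among cultured cells on the 20 cultured libraries and the 3 culture comparisons on the 20 libraries without lactate, with group means and no block. Gene lists were tested with camera at its preset correlation of 0.01 between genes, adjusted over 31 lists of pathways and cell markers written from general knowledge. The adjusted p of a list with the correlation estimated from the data is given beside it. Comparisons, tests, lists, the rule for named genes and the alternatives were set before the data were examined.

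The genes named are of 3 kinds. First come the 6 largest rises and 6 largest falls of each of the first 5 comparisons (4 and 4 of the others) among genes that passed, had an average log2 CPM of at least 5 and, outside the interactions, did not overlap between the groups, passing over predicted, mitochondrial, ribosomal and antigen receptor genes. Then, for each list with at least 3 members past the threshold, come the 2 with the smallest p. H2-Ab1, Cd74, Arg1, Mrc1, Nos2, Vegfa, Il1b and Ldhb were reported throughout. Examples come from these genes and list members. Where a symbol stood on more than 1 gene ID (126 symbols), the ID with the most reads was used for the lists.

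Whether replicate numbers pair the samples was checked from the correlation between deviations of same-number libraries from their group means. Fresh MHC-IIhi and MHC-IIlo had correlations of 0.155 to 0.685 with the same number the best partner in 4 of 5, so the numbers pair them, and a block on the number gave 5004 genes in place of 3737. No 2 libraries were identical, and chi-square per degree of freedom between libraries of a group was 9.99 to 276. The procedure was tested on simulated data with 200 changed genes per comparison. It recovered 75.8% to 98.4% of genes with a 4-fold change, 51.5% to 74.2% with a 2-fold and 5.97% to 54.5% with a 1.5-fold change, and 1.08% to 10.9% of its calls were false. Whether this holds for paired or outlying libraries was not tested.

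Alternatives were RLE size factors, no filter on low counts, DESeq2 (Wald test), limma voom with quality weights, all 30 libraries in 1 fit, limma trend on log2(FPKM + 1) and log2(FPKM + 0.1) for genes with FPKM of at least 1 in 5 libraries, the replicate number as a block, and each library left out in turn. Added after the data were seen were a block on the header number in the cultured comparisons, leaving lactate MHC-IIlo 5 out of the fit, and both together. Raw reads were not used here, so trimming, alignment and assignment stand as deposited. Results of some single genes are not reported here.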

Results

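RNA sequencing measured gene expression in 30 libraries of macrophages taken from tumours that 3LL-R cells, a line of Lewis lung carcinoma, had formed under the skin of C57BL/6 mice. Sorting parted these tumour-associated macrophages by surface MHC class II, the molecule that shows antigen to CD4 T cells, into MHC-IIhi and MHC-IIlo cells. Of each subset, 5 libraries came from 30000 fresh cells lysed straight after the sort, 5 from 250000 cells kept in culture for 24 h without lactate and 5 from 250000 cells kept for 24 h with 20 mM sodium L-lactate. Total counts per library were 16913250 to 21407666 in fresh MHC-IIhi, 17838799 to 20999665 in fresh MHC-IIlo, 22030754 to 29152519 in no-lactate MHC-IIhi, 24050876 to 29928350 in no-lactate MHC-IIlo, 16965012 to 30135127 in lactate MHC-IIhi and 18752181 to 31481548 in lactate MHC-IIlo. The first principal component held 50.1% of the variance of log2 counts scaled to library size (CPM) and parted fresh from cultured libraries, and the second held 16.3% and parted the subsets. Levels below are mean CPM ± SD with n = 5 libraries per group, changes are log2 fold changes ± SE, and positions are those of GRCm38. Where a gene list has 1 count, the count over all genes and that adjusted over the list alone were equal. Libraries are named by group and number, for cultured ones the number in the column header.

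**Figure D1:**
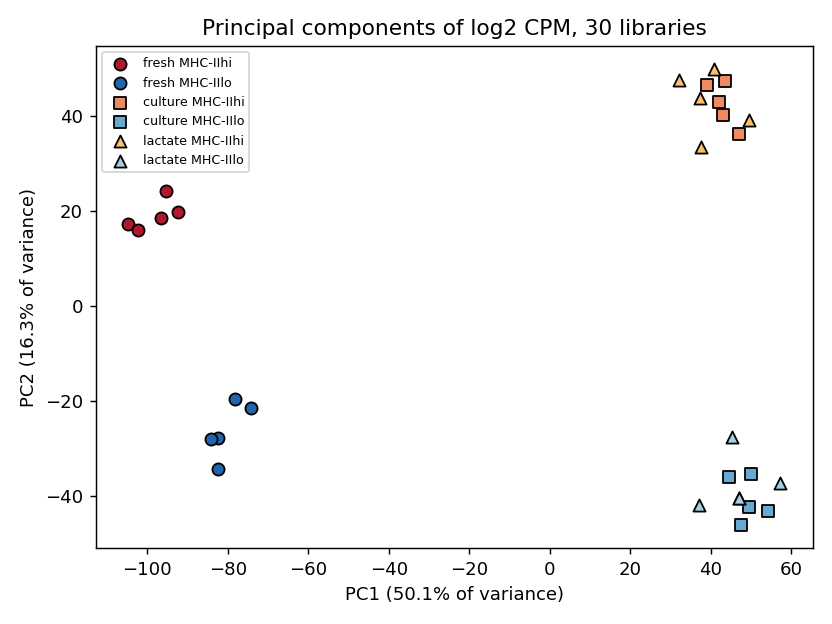
Each point is 1 of the 30 libraries, placed by its first principal component (x axis, 50.1% of variance) and second (y axis, 16.3%) of log2 CPM, with colour and shape giving the group. Fresh libraries sit apart from cultured ones on the x axis and MHC-IIhi from MHC-IIlo on the y axis.

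The first comparison asks how the MHC-IIlo and MHC-IIhi subsets differed straight from the tumour. H2-Ab1 (ENSMUSG00000073421, chromosome 17, 34263209 to 34269418), a chain of MHC class II, was at 89.1 ± 29.7 CPM in fresh MHC-IIlo against 4897 ± 472 CPM in MHC-IIhi (log2 fold change -5.77 ± 0.24, adjusted p = 5.4e-09). Cd163 (ENSMUSG00000008845, chromosome 6, 124304656 to 124330527), the scavenger receptor for haemoglobin, stood at 559 ± 141 CPM in MHC-IIlo and 98.2 ± 27.9 CPM in MHC-IIhi (log2 fold change 2.51 ± 0.21, adjusted p = 2.7e-06). Of 12787 genes tested with edgeR, 3737 differed, 1790 higher and 1947 lower in MHC-IIlo. The platelet chemokine Ppbp was higher (2.20), and the largest fall was that of Ccl17 (-7.13), a chemokine for T cells.

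Of the 12 tested genes of MHC class II presentation, 11 were lower in fresh MHC-IIlo, among them Cd74 (-4.35 ± 0.20), the invariant chain, and Ciita (-5.18 ± 0.35), the master regulator of the family, and 1, the protease Ctss, was higher. The MHC class II list had adjusted p = 1.3e-58, and adjusted p = 0.00135 with an estimated correlation. Macrophage identity genes had 8 higher and 1 lower of 14 (9 and 2 adjusted over the list alone), with Adgre1, which encodes F4/80, at 575 ± 115 against 184 ± 51.9 CPM and Mertk, a receptor for dead cells, at 1.04 (adjusted p = 0.0730 with all 30 libraries in the fit). The macrophage identity list had adjusted p = 0.00202, and adjusted p = 0.633 with an estimated correlation. Lipid handling genes had 11 higher and 4 lower of 19 (13 and 4 adjusted over the list alone). The scavenger receptor Cd36 was higher (1.36) and lipoprotein lipase Lpl lower (-1.26, adjusted p = 0.0867 with all 30 libraries in the fit). The lipid handling list had adjusted p = 0.00202, and adjusted p = 0.633 with an estimated correlation. Cholesterol synthesis and uptake genes were lower in 19 of 23 (21 adjusted over the list alone), as the kinase Pmvk (-0.84). The cholesterol list had adjusted p = 5.9e-08, and adjusted p = 0.430 with an estimated correlation. ATF4 targets, the amino acid stress genes, were lower in 7 of 18, with the amino acid transporter Slc7a5 at -1.28. The ATF4 target list had adjusted p = 0.00202, and adjusted p = 0.430 with an estimated correlation. Interferon-stimulated genes were higher in 10 and lower in 3 of 31 (11 and 3 adjusted over the list alone). The interferon list had adjusted p = 0.0272, and adjusted p = 0.726 with an estimated correlation. It did not pass with all 30 libraries in the fit (adjusted p = 0.0765). Matrix remodelling genes were higher in 9 and lower in 3 of 17 (9 and 5 adjusted over the list alone), with the protease inhibitor Timp2 at 1002 ± 192 against 345 ± 71.6 CPM. The matrix remodelling list had adjusted p = 0.0354, and adjusted p = 0.726 with an estimated correlation. Matrix remodelling genes lost their call at adjusted p = 0.0781 without fresh MHC-IIhi 3 and 0.0590 without fresh MHC-IIlo 4.

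Alternative activation genes went both ways in fresh cells, 9 higher and 7 lower in MHC-IIlo of 18 (list adjusted p = 0.981). The mannose receptor Mrc1 was at 7214 ± 1311 CPM in MHC-IIlo against 2943 ± 659.6 CPM in MHC-IIhi (1.30 ± 0.16, adjusted p = 6.8e-05), while Mgl2, a lectin of tumour macrophages (-2.21), and Pdcd1lg2, a ligand of PD-1 (-2.46), were lower. The Mrc1 call ended in the FPKM table, whose libraries share 1 distribution (0.19, adjusted p = 0.436). Arg1, which breaks down arginine, was at 3870.2 ± 663 CPM in MHC-IIlo against 2032 ± 609 CPM (0.93 ± 0.19, adjusted p = 0.00260), and its call ended there too (0.69, adjusted p = 0.0712). Il1b, a pyrogenic cytokine, was lower in MHC-IIlo (810.1 ± 265 against 1951 ± 637 CPM, adjusted p = 0.00127), a call lost with all 30 libraries in the fit (adjusted p = 0.0949). Nos2, which makes nitric oxide (0.12 ± 0.22), Vegfa, the vessel growth factor (0.12 ± 0.34), and Ldhb, a lactate dehydrogenase chain (0.32 ± 0.26), did not pass (adjusted p = 0.729, 0.838 and 0.413).

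Metabolic lists other than cholesterol and lipids did not pass in fresh cells. Glycolysis had 3 members higher and 3 lower in MHC-IIlo of 19 (list adjusted p = 0.128). TCA cycle genes had 2 higher and 8 lower of 23 (4 and 9 adjusted over the list alone, list adjusted p = 0.305). Nuclear genes of oxidative phosphorylation had 2 higher and 11 lower of 57 (1 and 9 adjusted over the list alone, list adjusted p = 0.0756). The pentose phosphate pathway had 1 higher and 5 lower of 12 (list adjusted p = 0.128). Fatty acid oxidation had 1 and 4 of 19 (list adjusted p = 0.734), and lactate and pyruvate handling 3 and 3 of 14, as the lactate receptor Gpr132 at -1.06 (list adjusted p = 0.923). Mitochondrially encoded genes had a median of -0.06 (list adjusted p = 0.981) and proliferation genes one of 0.08 (list adjusted p = 0.587). Hypoxia genes had 5 higher and 3 lower of 20 (6 and 3 adjusted over the list alone, list adjusted p = 0.488). Arginine and polyamine genes had 3 higher and 4 lower of 17 (5 and 5 adjusted over the list alone, list adjusted p = 0.442). Inflammatory mediators had 7 higher and 1 lower of 22 (7 and 2 adjusted over the list alone), with the monocyte chemokines Ccl2 at 2925 ± 855 against 954 ± 345 CPM (list adjusted p = 0.0734). Checkpoint ligands had 5 higher and 2 lower of 15 (list adjusted p = 0.981). NRF2 targets had 5 and 2 of 16 (list adjusted p = 0.147), and NFAT5 targets 1 lower of 8 (list adjusted p = 0.981). Immediate early genes had 6 lower of 20 (list adjusted p = 0.151). Some lists passed with 1 library left out. The glycolysis list had adjusted p = 0.0478 without fresh MHC-IIlo 4. The nuclear oxidative phosphorylation list had adjusted p = 0.0295 without fresh MHC-IIhi 1 and 0.0196 without 2. The inflammatory mediator list had adjusted p = 0.0314 without fresh MHC-IIhi 4, 0.0401 without 5, 0.0447 without fresh MHC-IIlo 1, 0.0198 without 2 and 0.0451 without 3. The immediate early list had adjusted p = 0.0446 without fresh MHC-IIhi 2 and 0.0206 without fresh MHC-IIlo 4. With the replicate number as a block, adjusted p was 1.4e-04 for inflammatory mediators, 0.00991 for immediate early genes and 0.0234 for NRF2 targets.

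Dendritic cell markers were lower in fresh MHC-IIlo in 7 of 10 (8 adjusted over the list alone), as the lectin Cd209a (-4.67, or -5.26 without fresh MHC-IIlo 2) and the transcription factor Batf3 (-2.30). The dendritic cell list had adjusted p = 0.00122, and adjusted p = 0.385 with an estimated correlation. Neutrophil markers were higher in 7 of 8 (8 adjusted over the list alone), with the collagenase Mmp8 at 433 ± 102 against 176 ± 48.1 CPM and S100a8 at 15.96 ± 3.08 against 8.09 ± 1.15 CPM. The neutrophil list had adjusted p = 7.3e-04, and adjusted p = 0.385 with an estimated correlation. Fibroblast markers were higher in 5 of 9 (6 adjusted over the list alone), as the collagen Col5a1 at 6.65 ± 1.81 against 2.07 ± 1.14 CPM. The fibroblast list had adjusted p = 0.0362, and adjusted p = 0.633 with an estimated correlation. Fibroblast genes lost their call at adjusted p = 0.0523 without fresh MHC-IIhi 4, 0.0873 without 5, 0.0765 without fresh MHC-IIlo 2 and 0.0754 without 3. Under the replicate block the fibroblast list did not pass (adjusted p = 0.107). T and NK cell markers were lower in 3 of 6 (4 adjusted over the list alone), as granzyme Gzmb at 1.39 ± 0.841 against 6.52 ± 1.24 CPM. The T and NK cell list had adjusted p = 0.0362, and adjusted p = 0.430 with an estimated correlation. That list did not pass under the replicate block either (adjusted p = 0.107). B cell markers were lower in 3 of 4, as Ighm, the heavy chain of IgM (-3.13). The B cell list had adjusted p = 0.0256, and adjusted p = 0.480 with an estimated correlation. Monocyte markers had 1 higher, the clotting factor F13a1 (1.84), and 3 lower, among them the chemokine receptor Ccr2 (-1.42; list adjusted p = 0.442). Endothelial markers had 2 higher and 1 lower of 4 (list adjusted p = 0.188), and epithelial markers 1 lower of 4 (list adjusted p = 0.240).

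**Figure D2:**
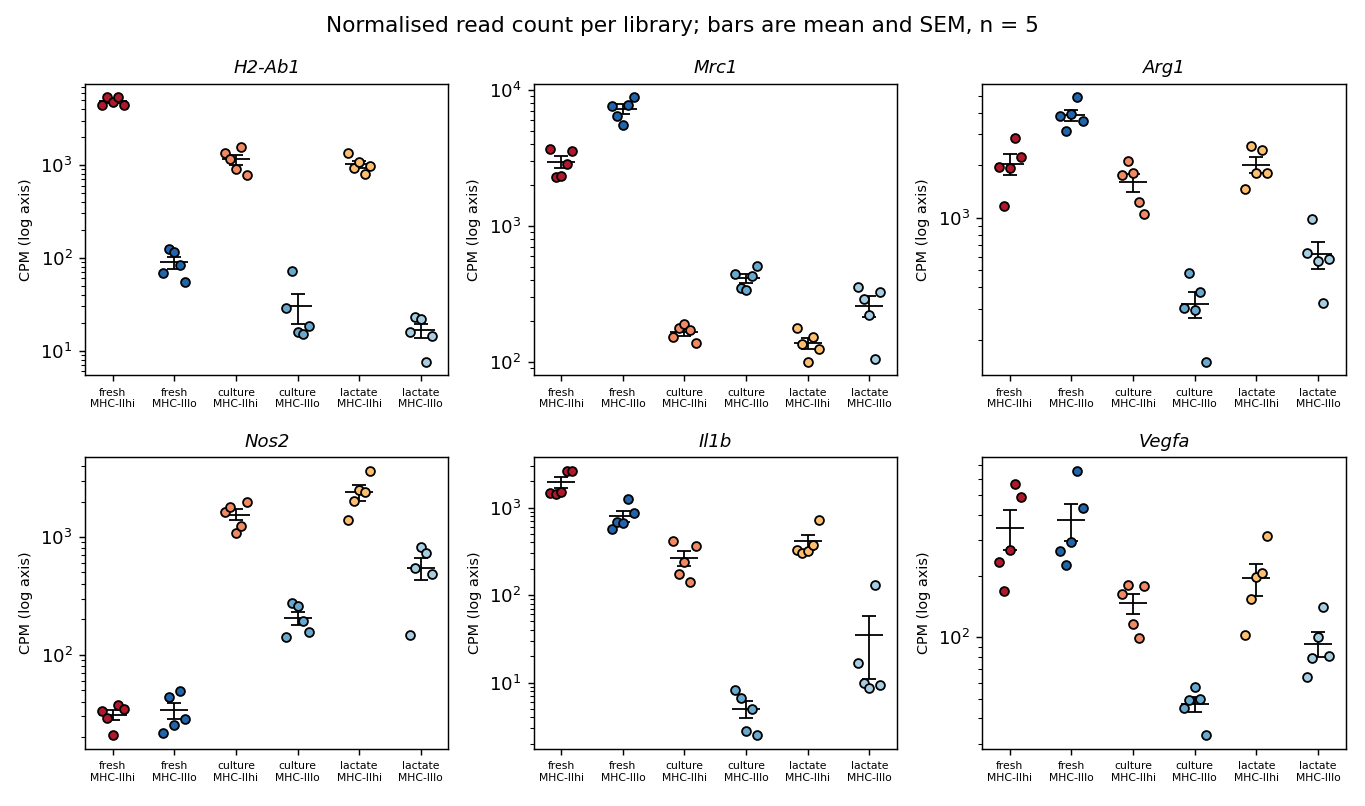
The 6 panels plot normalised read counts (CPM, log axis) of H2-Ab1, Mrc1, Arg1, Nos2, Il1b and Vegfa in the 6 groups, with 1 point per library and bars for mean and SEM (n = 5). H2-Ab1 was lower in MHC-IIlo when fresh (89.1 against 4897 CPM in the means) and after culture, and Nos2 was higher after culture in both subsets.

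The next comparison asks how the subsets differed after 24 h in culture without lactate. Cultured MHC-IIlo cells again had little H2-Ab1 (29.96 ± 23.9 CPM against 1151 ± 322 CPM in MHC-IIhi, -5.25 ± 0.43, adjusted p = 3.0e-08). Il1b (ENSMUSG00000027398, chromosome 2, 129364570 to 129371139) was at 5.04 ± 2.47 CPM in MHC-IIlo against 269 ± 121 CPM (-5.73 ± 0.75, adjusted p = 9.7e-06), and the chemokine Ccl22 (-8.14) and the receptor Ccr7 (-7.47), which steers cells to lymph nodes, were among the largest falls. Without no-lactate MHC-IIlo 3 these were -5.88 for H2-Ab1, -8.91 for Ccl22 and -9.24 for Ccr7. Higher in MHC-IIlo were Gas6, a ligand of Mertk, at 108 ± 25.6 against 13.8 ± 5.96 CPM (2.98 ± 0.38, adjusted p = 6.7e-06) and the lipid carrier Apoe (2.20). Of 13593 genes tested, 2830 differed, 1250 higher and 1580 lower in MHC-IIlo, and 1595 higher and 1154 lower in the FPKM table. Of the genes called in fresh and in cultured cells, 554 were higher in MHC-IIlo in both, where independent calls would share 166, and 575 were lower in both (210.0 for independent calls), while 98 went from higher to lower and 49 from lower to higher.

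In cultured cells 5 lists had a call that held with an estimated correlation. MHC class II genes were lower in cultured MHC-IIlo in 11 of 13, as Cd74 at -4.86, and dendritic cell markers in 9 of 9, with the growth factor receptor Flt3 at 0.129 ± 0.226 against 29.1 ± 13.5 CPM. The MHC class II list had adjusted p = 6.9e-16, and adjusted p = 0.0277 with an estimated correlation. The dendritic cell list had adjusted p = 6.9e-16, and adjusted p = 0.00654 with an estimated correlation. Flt3 had -7.75, and -9.76 without no-lactate MHC-IIlo 3. Inflammatory mediators had 16 lower and 1 higher, Ccl7, of 24 (16 and 2 adjusted over the list alone), with the neutrophil chemokine Cxcl3 at 97.6 ± 35.9 against 842 ± 202 CPM and the cytokine subunit Il12b at -7.21, or -8.29 without no-lactate MHC-IIlo 4. The inflammatory mediator list had adjusted p = 4.8e-11, and adjusted p = 0.0277 with an estimated correlation. Checkpoint ligands and suppressive factors were lower in 11 of 17 (11 lower and 1 higher adjusted over the list alone), with Pdcd1lg2 at -4.37 and Nos2 at 205 ± 58.9 against 1551 ± 378 CPM. The checkpoint list had adjusted p = 9.2e-07, and adjusted p = 0.00654 with an estimated correlation. Immediate early genes were lower in 11 and higher in 1 of 20 (12 and 2 adjusted over the list alone). The immediate early list had adjusted p = 0.00116, and adjusted p = 0.0442 with an estimated correlation.

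Glycolysis genes were lower in cultured MHC-IIlo in 15 of 19, as the kinase Pfkfb3 at 154 ± 11.6 against 436 ± 26.1 CPM. The glycolysis list had adjusted p = 4.3e-14, and adjusted p = 0.0538 with an estimated correlation. Hypoxia genes were lower in 17 of 20, with Ddit4, a brake on mTOR, at -3.38 and Vegfa at 46.9 ± 8.96 against 147 ± 37.2 CPM. The hypoxia list had adjusted p = 1.1e-10, and adjusted p = 0.170 with an estimated correlation. Mitochondrially encoded genes were lower in 6 of 7, as mt-Nd1 at -1.35, but in 1 of 7 in the FPKM table, where mt-Co1 lost its call (-0.08, adjusted p = 0.627). The mitochondrially encoded list had adjusted p = 0.00102, and adjusted p = 0.246 with an estimated correlation. ATF4 targets were lower in 7 of 18 (9 adjusted over the list alone). The ATF4 target list had adjusted p = 9.1e-04, and adjusted p = 0.433 with an estimated correlation. Arginine and polyamine genes were lower in 5 of 17, with Arg1 at 322 ± 122 against 1595 ± 438 CPM and Ass1, which rebuilds arginine, at -2.59. The arginine and polyamine list had adjusted p = 0.00233, and adjusted p = 0.127 with an estimated correlation. Alternative activation genes had 4 higher, among them Mrc1 at 414 ± 70.1 against 166 ± 21.2 CPM, and 5 lower of 16 (4 and 6 adjusted over the list alone). The alternative activation list had adjusted p = 0.00213, and adjusted p = 0.137 with an estimated correlation. Lipid handling genes were higher in 9 and lower in 1 of 19 (11 and 1 adjusted over the list alone), as Apoe at 1435 ± 267 against 314 ± 44.8 CPM, while the call of Gpnmb, a lysosomal glycoprotein, ended in the FPKM table (1.19 against 0.22, adjusted p = 0.216). The lipid handling list had adjusted p = 9.3e-05, and adjusted p = 0.324 with an estimated correlation. Cholesterol genes were lower in 8 of 23 (11 adjusted over the list alone). The cholesterol list had adjusted p = 0.0182, and adjusted p = 0.433 with an estimated correlation. Cholesterol genes lost their call at adjusted p = 0.0775 without no-lactate MHC-IIhi 5.

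Monocyte markers were lower in cultured MHC-IIlo in 6 and higher in 1 of 8, with the proteoglycan Vcan at 66.9 ± 20.2 against 257 ± 26.8 CPM. The monocyte list had adjusted p = 0.00542, and adjusted p = 0.245 with an estimated correlation. T and NK cell markers were lower in 3 of 4, as Gzmb at 2.30 ± 1.098 against 9.08 ± 3.23 CPM. The T and NK cell list had adjusted p = 0.0385, and adjusted p = 0.298 with an estimated correlation. T and NK cell genes lost their call at adjusted p = 0.0726 without no-lactate MHC-IIhi 3, 0.0674 without 5 and 0.0551 without no-lactate MHC-IIlo 6. The call also ended with lactate MHC-IIlo 5 left out of the fit (adjusted p = 0.0536). Epithelial markers were lower in 2 of 4, Epcam and the cadherin Cdh1 (-4.79 and -2.37), though the median of the 3 members in the FPKM table was above 0 (0.15). The epithelial list had adjusted p = 0.00843, and adjusted p = 0.0668 with an estimated correlation. In all, 16 of 31 lists passed, and Ldhb did not differ past the threshold (0.11 ± 0.56, adjusted p = 0.922).

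The lactate comparisons ask what 20 mM sodium lactate changed in cultured cells of each subset. In MHC-IIhi few transcripts moved. Olfml2b (ENSMUSG00000038463, chromosome 1, 170644532 to 170682789), a secreted matrix protein, rose from 55.5 ± 9.65 to 164 ± 41.2 CPM (1.57 ± 0.18, adjusted p = 3.4e-04). The lipid enzymes Smpdl3b (1.15 ± 0.16, adjusted p = 0.00271) and Sgms2, which makes sphingomyelin (0.76 ± 0.11, adjusted p = 0.00271), rose as well, and Slc16a6, a carrier of the monocarboxylate family, fell from 46.5 ± 7.52 to 22.5 ± 3.88 CPM (-1.04 ± 0.15, adjusted p = 0.00335). Of 13593 genes tested 34 passed, 28 higher and 6 lower, and limma on FPKM called 30 higher and 12 lower. Before adjustment 1342 genes lay under p of 0.05, where chance gives 679.6. The count was 131 with DESeq2, 53 with all 30 libraries in the fit, 54 with lactate MHC-IIlo 5 left out of it, 81 with the header-number block and 255 with the block and without that library. It was 19 without no-lactate MHC-IIhi 3, 13 without 4, 10 without 5 and 8 without 6, and 12 without lactate MHC-IIhi 1, 8 without 3, 21 without 4, 22 without 5 and 9 without 6.

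Other genes passed in MHC-IIhi with all libraries and not without some of them. Fibronectin Fn1 was at 106 ± 27.4 CPM without and 353 ± 113 CPM with lactate (1.75 ± 0.33, adjusted p = 0.0253). Fn1 lost its call at adjusted p = 0.0650 without no-lactate MHC-IIhi 3, 0.0558 without 4, 0.0731 without 5, 0.0935 without 6, 0.0622 without 7, 0.0684 without lactate MHC-IIhi 1, 0.0852 without 3 and 0.0584 without 6. The collagenase Mmp8 was at 767 ± 133 and 1783 ± 289 CPM (1.23 ± 0.26, adjusted p = 0.0472; adjusted p = 0.0530 with RLE size factors and 0.0780 with the header-number block). Mmp8 lost its call at adjusted p = 0.148 without no-lactate MHC-IIhi 3, 0.0656 without 4, 0.127 without 5, 0.113 without 6, 0.131 without 7, 0.0741 without lactate MHC-IIhi 1, 0.156 without 3, 0.0619 without 4, 0.101 without 5 and 0.109 without 6. H2-Ab1 (-0.16 ± 0.36), Cd74 (-0.26 ± 0.36), Arg1 (0.35 ± 0.29), Mrc1 (-0.26 ± 0.23), Nos2 (0.64 ± 0.33), Vegfa (0.41 ± 0.25), Il1b (0.62 ± 0.60) and Ldhb (0.47 ± 0.56) did not pass, with adjusted p from 0.545 for Nos2 to 0.923 for H2-Ab1.

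With lactate in MHC-IIhi 11 lists moved as a whole, though few of their members passed singly and each list call was lost with an estimated correlation. Glycolysis genes moved up (median 0.25), as did mitochondrially encoded genes (median 0.39). The glycolysis and mitochondrially encoded lists each had adjusted p = 1.2e-04, and adjusted p = 0.493 with an estimated correlation. Hypoxia genes (median 0.34) and NRF2 targets (median 0.19) moved the same way. The hypoxia list had adjusted p = 1.2e-04, and adjusted p = 0.597 with an estimated correlation. The NRF2 target list had adjusted p = 0.00127, and adjusted p = 0.493 with an estimated correlation. So did NFAT5 targets (median 0.34) and matrix remodelling genes (median 0.09). The NFAT5 target list had adjusted p = 1.2e-04, and adjusted p = 0.0855 with an estimated correlation. The matrix remodelling list had adjusted p = 0.0138, and adjusted p = 0.493 with an estimated correlation. Among their members 1 NRF2 target (3 adjusted over the list alone), 1 NFAT5 target, the betaine carrier Slc6a12 (2.56; 2 adjusted over the list alone), and 2 matrix genes (5 adjusted over the list alone) rose. Proliferation genes moved down (median -0.28), and so did interferon-stimulated genes (median -0.25). The proliferation list had adjusted p = 3.1e-06, and adjusted p = 0.597 with an estimated correlation. The interferon list had adjusted p = 2.6e-04, and adjusted p = 0.657 with an estimated correlation. ATF4 targets (median -0.28), alternative activation genes (median -0.29) and T and NK cell markers (median -1.01) moved down too. The ATF4 target list had adjusted p = 0.00233, and adjusted p = 0.657 with an estimated correlation. The alternative activation list had adjusted p = 0.0263, and adjusted p = 0.493 with an estimated correlation. The T and NK cell list had adjusted p = 0.00227, and adjusted p = 0.493 with an estimated correlation. For 6 of these lists the call hung on single libraries. Hypoxia genes lost their call at adjusted p = 0.0547 without lactate MHC-IIhi 6. NRF2 target genes lost their call at adjusted p = 0.0644 without no-lactate MHC-IIhi 5, and matrix remodelling genes at 0.0576 without 6. Interferon genes lost their call at adjusted p = 0.109 without no-lactate MHC-IIhi 6 and 0.0673 without lactate MHC-IIhi 6. ATF4 target genes lost their call at adjusted p = 0.0800 without no-lactate MHC-IIhi 7. Alternative activation genes lost their call at adjusted p = 0.0781 without no-lactate MHC-IIhi 3, 0.0658 without 4, 0.0647 without lactate MHC-IIhi 4 and 0.0551 without 5. ATF4 targets did not pass with the header-number block either (adjusted p = 0.361, or 0.264 with lactate MHC-IIlo 5 left out as well).

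**Figure D3:**
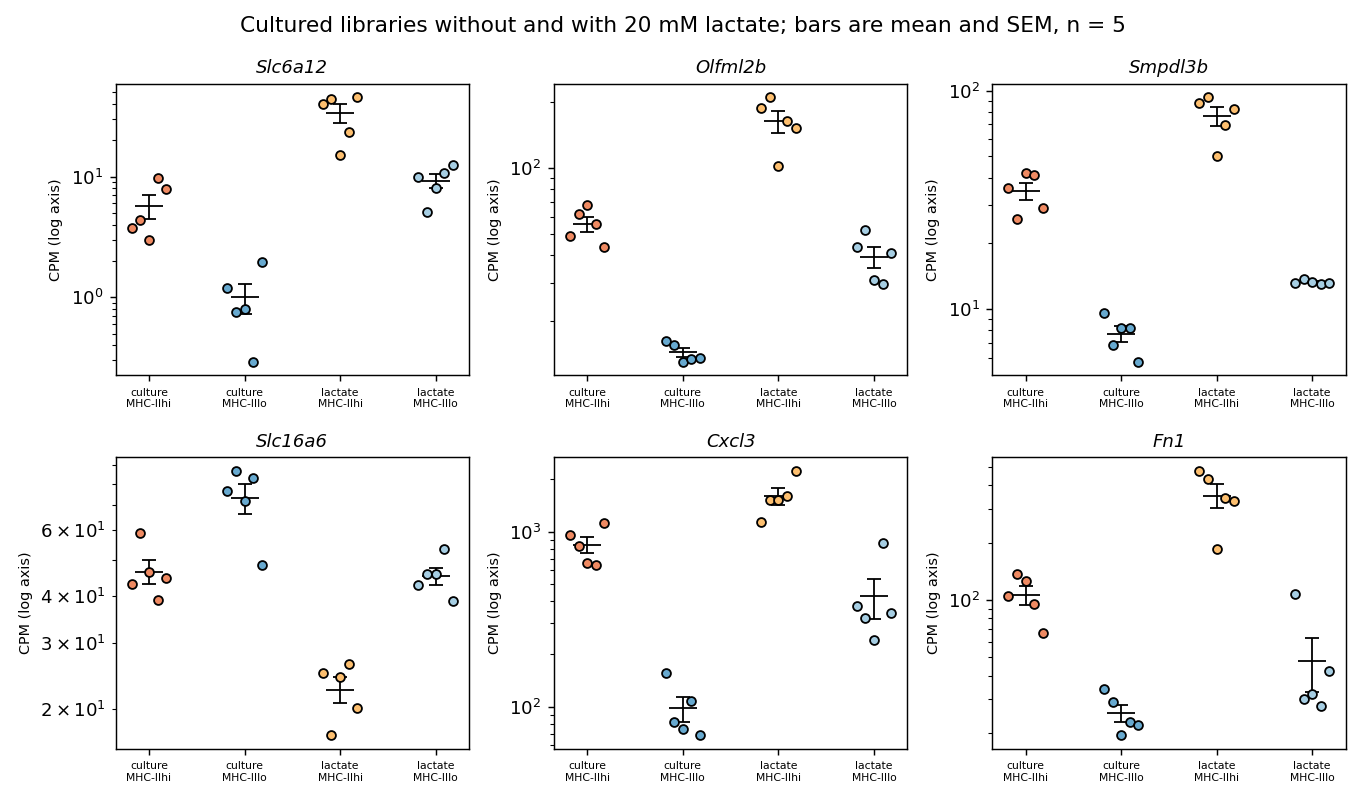
The 6 panels plot normalised read counts (CPM, log axis) of Slc6a12, Olfml2b, Smpdl3b, Slc16a6, Cxcl3 and Fn1 in the 4 cultured groups, with 1 point per library and bars for mean and SEM (n = 5). Olfml2b rose with lactate in MHC-IIhi from 55.5 to 164 CPM in the means, and Cxcl3 rose in MHC-IIlo from 97.6 to 428 CPM.

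In MHC-IIlo cells lactate raised chemokines that draw neutrophils. Cxcl3 (ENSMUSG00000029379, chromosome 5, 90786103 to 90789600) rose from 97.6 ± 35.9 to 428 ± 246 CPM (2.14 ± 0.31, adjusted p = 0.00348), Cxcl1 from 16.1 ± 4.89 to 101 ± 108 CPM (2.66 ± 0.47, adjusted p = 0.00821) and Cxcl2 from 35.4 ± 10.51 to 208 ± 227 CPM (2.56 ± 0.48, adjusted p = 0.0126). Lactate MHC-IIlo 5 stood far above the other libraries of its group in the 3 chemokines (858, 292 and 611 CPM). Without it they still passed, at 1.72, 1.74 and 1.61 (adjusted p = 0.00226, 0.0104 and 0.0136). The organic anion carrier Slco4a1 rose (1.88 ± 0.33, adjusted p = 0.00821), and the integrin Itga6 (-1.13 ± 0.19, adjusted p = 0.00819) fell. Of 13593 genes tested 202 passed, 123 higher and 79 lower, and 2373 lay under p of 0.05 before adjustment where chance gives 679.6. Counts were 689 with DESeq2, 1502 with limma voom, 531 with all 30 libraries in the fit, 1111 with the header-number block and 631 with that block and lactate MHC-IIlo 5 left out. Leaving out no-lactate MHC-IIlo 1, 3, 4, 5 or 6 gave 60, 80, 121, 63 or 53 genes, and leaving out lactate MHC-IIlo 1, 3, 4, 5 or 6 gave 758, 86, 56, 133 or 74. The design holds no group with the same amount of another sodium salt.

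Other genes passed in MHC-IIlo with all libraries and not without some of them. Il1b was at 5.04 ± 2.47 CPM without and 34.7 ± 52.8 CPM with lactate (2.79 ± 0.67, adjusted p = 0.0413; adjusted p = 0.135 with FPKM, 0.0628 with limma voom and 0.0846 with the header-number block and lactate MHC-IIlo 5 left out). Il1b lost its call at adjusted p = 0.0735 without no-lactate MHC-IIlo 1, 0.0834 without 3, 0.0811 without 4, 0.0956 without 5, 0.109 without 6 and 0.144 without lactate MHC-IIlo 5. Its change was 1.15 without lactate MHC-IIlo 5, which held 129 CPM. Nos2 was at 205 ± 58.9 and 548 ± 263 CPM (1.42 ± 0.34, adjusted p = 0.0401; adjusted p = 0.0819 with FPKM). Nos2 lost its call at adjusted p = 0.110 without no-lactate MHC-IIlo 1, 0.0608 without 3, 0.0567 without 4, 0.0952 without 5, 0.106 without 6, 0.0774 without lactate MHC-IIlo 3, 0.0984 without 4, 0.0721 without 5 and 0.0696 without 6. Ddit4 had 1.66 ± 0.36 (adjusted p = 0.0239). Ddit4 lost its call at adjusted p = 0.0652 without no-lactate MHC-IIlo 3, 0.0659 without 5, 0.0691 without 6, 0.0545 without lactate MHC-IIlo 4 and 0.0564 without 5. H2-Aa, the other chain of MHC class II, had -2.20 ± 0.51 (adjusted p = 0.0367). H2-Aa lost its call at adjusted p = 0.0685 without no-lactate MHC-IIlo 1, 0.115 without 3, 0.0535 without 6, 0.0870 without lactate MHC-IIlo 4, 0.0564 without 5 and 0.0864 without 6. H2-Ab1 (-0.86 ± 0.37, adjusted p = 0.220), Cd74 (-0.88 ± 0.37, adjusted p = 0.208), Mrc1 (-0.67 ± 0.23, adjusted p = 0.126) and Ldhb (-0.23 ± 0.56, adjusted p = 0.867) did not pass. No-lactate MHC-IIlo 3 was high in MHC class II genes, and without it H2-Ab1 had -0.24, Cd74 -0.35 and H2-Aa -1.36. Arg1 (0.94 ± 0.29, adjusted p = 0.0934) and Vegfa (0.99 ± 0.25, adjusted p = 0.0523) did not pass either. Under alternatives Arg1 passed with DESeq2 (adjusted p = 0.0296), limma voom (0.00658), all 30 libraries (0.0477), the header block (0.0251) and that block without lactate MHC-IIlo 5 (0.00298). Vegfa passed with DESeq2 (adjusted p = 0.00826), limma voom (0.00602), no filter (0.0454), the header block (0.0271) and without lactate MHC-IIlo 1 (0.0207), and Mrc1 with limma voom (0.0251) and with the block and without lactate MHC-IIlo 5 (0.0453).

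With lactate in MHC-IIlo 11 lists moved, each losing its call with an estimated correlation. Hypoxia genes moved up (median 0.75), 1 of 20 rising over all genes and 15 adjusted over the list alone, and glycolysis genes likewise (median 0.52, 1 and 15 of 19). The hypoxia list had adjusted p = 4.5e-11, and adjusted p = 0.361 with an estimated correlation. The glycolysis list had adjusted p = 4.5e-11, and adjusted p = 0.275 with an estimated correlation. Inflammatory mediators had 6 rises and 1 fall of 24 (11 and 1 adjusted over the list alone). The inflammatory mediator list had adjusted p = 1.1e-05, and adjusted p = 0.301 with an estimated correlation. NFAT5 targets, the genes of hyperosmotic stress, moved up with 2 rises of 9 (6 adjusted over the list alone), among them Slc6a12 (3.19 ± 0.43). The NFAT5 target list had adjusted p = 4.6e-05, and adjusted p = 0.0670 with an estimated correlation. NRF2 targets moved up with 1 rise (5 adjusted over the list alone), arginine and polyamine genes with 1 (2 adjusted over the list alone), mitochondrially encoded genes by a median of 0.38 and nuclear genes of oxidative phosphorylation by 0.08. The NRF2 target list had adjusted p = 5.7e-05, and adjusted p = 0.361 with an estimated correlation. The arginine and polyamine list had adjusted p = 0.0165, and adjusted p = 0.361 with an estimated correlation. The mitochondrially encoded list had adjusted p = 0.00601, and adjusted p = 0.519 with an estimated correlation. Mitochondrially encoded genes lost their call at adjusted p = 0.0518 without no-lactate MHC-IIlo 3 and 0.0531 without lactate MHC-IIlo 5. The nuclear oxidative phosphorylation list had adjusted p = 0.0175, and adjusted p = 0.811 with an estimated correlation. Nuclear oxidative phosphorylation genes lost their call at adjusted p = 0.0693 without no-lactate MHC-IIlo 4, 0.0590 without 5, 0.0620 without 6, 0.345 without lactate MHC-IIlo 3 and 0.127 without 4. MHC class II genes moved down, 2 of 13 falling (3 adjusted over the list alone). The MHC class II list had adjusted p = 0.00368, and adjusted p = 0.519 with an estimated correlation. MHC class II genes lost their call at adjusted p = 0.0794 without lactate MHC-IIlo 5. Without no-lactate MHC-IIlo 3, high in these genes, the list had adjusted p = 0.0302. Interferon-stimulated genes moved down by a median of -0.34 and lipid handling genes by -0.20. The interferon list had adjusted p = 1.1e-06, and adjusted p = 0.519 with an estimated correlation. The lipid handling list had adjusted p = 0.0245, and adjusted p = 0.697 with an estimated correlation. Lipid handling genes lost their call at adjusted p = 0.0722 without no-lactate MHC-IIlo 3 and 0.551 without lactate MHC-IIlo 5. With the header-number block and lactate MHC-IIlo 5 left out that list had adjusted p = 0.0754. T and NK cell markers, 1 of 14 at 1 CPM or more in both subsets, did not pass (median -1.19, adjusted p = 0.0760). They did at adjusted p = 0.0347 without no-lactate MHC-IIlo 1, 0.0458 without 4 and 0.00517 without 6. It was 0.0177 without lactate MHC-IIlo 3, 0.00221 without 4, 0.0476 without 5, 0.00698 with no filter and 0.0388 with all 30 libraries. Ribosomal RNA made up 0.0605% to 0.229% of counts with and 0.0434% to 0.0562% without lactate, and mitochondrial genes 0.280% to 0.623% and 0.209% to 0.338%. Lactate MHC-IIlo 5 stood apart from its group in the share of counts in its 10 most abundant genes (7.16%).

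Some genes answered lactate in both subsets. Of the genes called, 10 rose in both where independent calls would share 0.253, and 2 fell in both (0.0349 for independent calls). These genes, named after their values were seen, were led by Slc6a12 (ENSMUSG00000030109), which carries the osmolyte betaine (2.56 ± 0.38 in MHC-IIhi and 3.19 ± 0.43 in MHC-IIlo, adjusted p = 0.00335 and 0.00209). The others that rose were Stfa3, Olfml2b (1.57 ± 0.18 and 1.45 ± 0.18), Slc39a4, the collagen receptor Itga1, Smpdl3b, Sort1, Nicn1, Sgms2 and Tuba4a. Slc16a6 (-1.04 ± 0.15 and -0.69 ± 0.15) and the VEGF receptor Flt1 (-1.08 ± 0.22 and -1.14 ± 0.22) fell in both.

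The interaction asks whether lactate acted differently in MHC-IIlo and MHC-IIhi. edgeR called 0 of 13593 genes, with 1018 under p of 0.05 before adjustment where chance gives 679.6. DESeq2 called 2, limma voom 2, edgeR with all 30 libraries 1, edgeR with RLE size factors 0, edgeR with no filter 0 and limma on FPKM 0. Bcl2a1a, a survival gene of the Bcl2 family named after its values were seen, was called by DESeq2 (1.03, adjusted p = 0.00523), limma voom (1.15, adjusted p = 0.0123) and edgeR with all 30 libraries (adjusted p = 0.0170). The other calls were Gm1840 with DESeq2 (adjusted p = 0.0218) and Il22 with limma voom (adjusted p = 0.00234). Without lactate MHC-IIlo 1 edgeR called 8 genes, Bcl2a1a among them, and without no-lactate MHC-IIhi 7 it called 1. Il1b (2.17 ± 0.88, adjusted p = 0.661), Nos2 (0.78 ± 0.47), Arg1 (0.60 ± 0.41), Vegfa (0.58 ± 0.36), H2-Ab1 (-0.71 ± 0.51), Cd74 (-0.62 ± 0.51), Mrc1 (-0.42 ± 0.32) and Ldhb (-0.70 ± 0.79) did not differ in their lactate change past the threshold. Single libraries carried some of these values, as Il1b had 0.54 and Mrc1 -0.20 without lactate MHC-IIlo 5, and H2-Ab1 -0.07 and Cd74 -0.07 without no-lactate MHC-IIlo 3.

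By lists, the lactate change differed between the subsets in 8, all losing their call with an estimated correlation (each at adjusted p = 0.842 with an estimated correlation). MHC class II genes moved lower with lactate in MHC-IIlo than in MHC-IIhi (median difference -0.71, adjusted p = 0.00110). ATF4 targets (0.50, adjusted p = 3.8e-04), inflammatory mediators (0.70, adjusted p = 0.00110), glycolysis (0.29, adjusted p = 0.00280), nuclear oxidative phosphorylation (0.11, adjusted p = 0.00110), hypoxia (0.33, adjusted p = 0.00300), arginine and polyamine genes (0.38, adjusted p = 0.00531) and proliferation (0.30, adjusted p = 0.00110) moved higher in MHC-IIlo than in MHC-IIhi. Hypoxia genes lost their call at adjusted p = 0.0791 without no-lactate MHC-IIhi 7 and 0.211 without lactate MHC-IIhi 1. Proliferation genes lost their call at adjusted p = 0.0914 without no-lactate MHC-IIhi 5, 0.0944 without lactate MHC-IIhi 1 and 0.0726 without lactate MHC-IIlo 5. A block on the header number ended the calls of glycolysis (adjusted p = 0.0508) and hypoxia (0.391). With that block and lactate MHC-IIlo 5 left out, adjusted p was 0.0733 for glycolysis, 0.764 for hypoxia, 0.618 for ATF4 targets, 0.0908 for MHC class II and 0.0743 for proliferation genes.

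The culture comparisons ask what 24 h without lactate changed. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), a sensor of viral RNA, rose in MHC-IIhi from 19.4 ± 2.69 to 989.8 ± 264 CPM (5.68 ± 0.18, adjusted p = 4.7e-16). Fn1 (ENSMUSG00000026193, chromosome 1, 71585520 to 71653200) fell in MHC-IIhi from 17797 ± 2951 to 106 ± 27.4 CPM (-7.39 ± 0.26, adjusted p = 1.2e-15) and in MHC-IIlo from 9005 ± 1767 to 25.4 ± 5.95 CPM (-8.46 ± 0.27). Another large rise was that of Cd200, a brake on myeloid cells (7.70 and 6.71 in MHC-IIhi and MHC-IIlo). Large falls were those of Fosb (-9.33 and -10.13), Cd163 (-7.22 and -8.05) and Il1b (-2.85 and -7.32). Of 13682 genes 8484 changed in MHC-IIhi, 4318 up and 4166 down, and 7867 in MHC-IIlo, 3780 up and 4087 down. Of these 3043 rose and 3058 fell in both, where independent calls would share 1193 and 1244. Culture goes together with the number of cells and the way of lysis, so the comparison covers the procedures as wholes.

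Interferon-stimulated genes rose in 30 of 31 in MHC-IIhi and in 30 of 31 in MHC-IIlo, and the member that fell was the T cell chemokine Cxcl9 (-2.75 and -2.78). The interferon list had adjusted p = 1.0e-61 in MHC-IIhi (adjusted p = 0.0197 with an estimated correlation) and 4.5e-62 in MHC-IIlo (adjusted p = 0.00703 with an estimated correlation). Immediate early genes fell in 18 of 20 in MHC-IIhi and 19 in MHC-IIlo, as Egr1 (-6.08 and -6.43). The immediate early list had adjusted p = 5.3e-19 in MHC-IIhi (adjusted p = 0.0695 with an estimated correlation) and 2.9e-25 in MHC-IIlo (adjusted p = 0.0286 with an estimated correlation). Alternative activation genes fell in 15 of 18 in MHC-IIhi, where Ccl22 rose (4.00), and in 16 in MHC-IIlo, with Mrc1 at 7214 ± 1311 CPM fresh and 414 ± 70.1 CPM cultured in MHC-IIlo. The alternative activation list had adjusted p = 1.8e-06 in MHC-IIhi (adjusted p = 0.0695 with an estimated correlation) and 1.6e-12 in MHC-IIlo (adjusted p = 0.00703 with an estimated correlation). Lipid handling genes rose in 13 and fell in 2 of 19 in MHC-IIhi and rose in 14 and fell in 2 in MHC-IIlo (14 and 3 adjusted over the list alone), with Gpnmb at 5.18 and 5.54. The lipid handling list had adjusted p = 2.3e-04 in MHC-IIhi (adjusted p = 0.427 with an estimated correlation) and 2.5e-06 in MHC-IIlo (adjusted p = 0.240 with an estimated correlation). NRF2 targets rose in 15 of 16 in MHC-IIhi (16 adjusted over the list alone) and in 12 in MHC-IIlo with 1 fall. The NRF2 target list had adjusted p = 1.8e-06 in MHC-IIhi (adjusted p = 0.241 with an estimated correlation) and 2.2e-04 in MHC-IIlo (adjusted p = 0.290 with an estimated correlation). MHC class II genes fell in 11 and rose in 1 of 13 in MHC-IIhi and fell in 10 and rose in 1 in MHC-IIlo, with H2-Ab1 at -2.09 and -1.56 (the latter -2.18 without no-lactate MHC-IIlo 3). The MHC class II list had adjusted p = 5.2e-07 in MHC-IIhi (adjusted p = 0.195 with an estimated correlation) and 0.00114 in MHC-IIlo (adjusted p = 0.320 with an estimated correlation).

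Mitochondrially encoded genes fell in 7 of 7 in MHC-IIhi and 7 in MHC-IIlo. The mitochondrially encoded list had adjusted p = 0.00955 in MHC-IIhi (adjusted p = 0.444 with an estimated correlation) and 2.5e-06 in MHC-IIlo (adjusted p = 0.142 with an estimated correlation). Nuclear genes of oxidative phosphorylation fell in 36 and rose in 1 of 58 in MHC-IIhi (37 and 1 adjusted over the list alone) and fell in 32 and rose in 3 in MHC-IIlo (34 and 3 adjusted over the list alone). The nuclear oxidative phosphorylation list had adjusted p = 2.3e-04 in MHC-IIhi (adjusted p = 0.572 with an estimated correlation) and 0.0166 in MHC-IIlo (adjusted p = 0.696 with an estimated correlation). TCA cycle genes fell in 17 and rose in 1 of 23 in MHC-IIhi and fell in 16 and rose in 1 in MHC-IIlo (16 and 2 adjusted over the list alone). The TCA cycle list had adjusted p = 3.4e-04 in MHC-IIhi (adjusted p = 0.183 with an estimated correlation) and 0.0192 in MHC-IIlo (adjusted p = 0.290 with an estimated correlation). Fatty acid oxidation genes fell in 16 of 19 in MHC-IIhi with 1 rise and in 13 in MHC-IIlo with 2 rises. The fatty acid oxidation list had adjusted p = 0.00102 in MHC-IIhi (adjusted p = 0.322 with an estimated correlation) and 0.00793 in MHC-IIlo (adjusted p = 0.320 with an estimated correlation). Cholesterol genes fell in 21 of 23 in MHC-IIhi and 18 in MHC-IIlo (19 adjusted over the list alone). The cholesterol list had adjusted p = 5.2e-07 in MHC-IIhi (adjusted p = 0.241 with an estimated correlation) and 1.0e-04 in MHC-IIlo (adjusted p = 0.290 with an estimated correlation). Proliferation genes rose in 21 of 26 in MHC-IIhi (22 adjusted over the list alone), as Pcna (0.86). The proliferation list had adjusted p = 0.0150, and adjusted p = 0.638 with an estimated correlation. Proliferation genes lost their call at adjusted p = 0.0507 without no-lactate MHC-IIhi 5. Monocyte markers fell in 5 and rose in 2 of 8 in MHC-IIhi and fell in 7 and rose in 1 in MHC-IIlo. The monocyte list had adjusted p = 0.0362 in MHC-IIhi (adjusted p = 0.444 with an estimated correlation) and 2.1e-04 in MHC-IIlo (adjusted p = 0.142 with an estimated correlation). Monocyte genes lost their call at adjusted p = 0.0577 without no-lactate MHC-IIhi 3 and 0.0699 without 7. In MHC-IIhi the monocyte list did not pass with all 30 libraries in the fit (adjusted p = 0.0533) or with the header-number block (0.0704). Endothelial markers rose in 3 of 4 in MHC-IIhi and rose in 2 and fell in 1 in MHC-IIlo, with the VEGF receptor Kdr at 6.80 and 5.11; with no filter on low counts neither call held (adjusted p = 0.156 and 0.839). The endothelial list had adjusted p = 0.00196 in MHC-IIhi (adjusted p = 0.0594 with an estimated correlation) and 0.0190 in MHC-IIlo (adjusted p = 0.142 with an estimated correlation).

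Further lists passed in MHC-IIlo. Of these, 2 passed in MHC-IIhi only when 1 library was left out, macrophage identity (adjusted p = 0.0303 without fresh MHC-IIhi 2 and 0.0292 without no-lactate MHC-IIhi 6) and matrix remodelling (0.0334 without fresh MHC-IIhi 2), and the other 5 did not pass there. In MHC-IIlo glycolysis genes fell in 13 and rose in 1 of 19, and hypoxia genes fell in 17 of 20, as Vegfa (375 ± 176 to 46.9 ± 8.96 CPM). The glycolysis list had adjusted p = 9.1e-04, and adjusted p = 0.372 with an estimated correlation. The hypoxia list had adjusted p = 2.5e-06, and adjusted p = 0.290 with an estimated correlation. Inflammatory mediators fell in 14 and rose in 3 of 24. The inflammatory mediator list had adjusted p = 0.0365, and adjusted p = 0.603 with an estimated correlation. Inflammatory mediator genes lost their call at adjusted p = 0.0544 without fresh MHC-IIlo 5, 0.0541 without no-lactate MHC-IIlo 3 and 0.0558 without 6. Matrix remodelling genes fell in 12 and rose in 1 of 17, and macrophage identity genes fell in 9 and rose in 3 of 14. The matrix remodelling list had adjusted p = 1.6e-04, and adjusted p = 0.197 with an estimated correlation. The macrophage identity list had adjusted p = 0.00394, and adjusted p = 0.417 with an estimated correlation. Neutrophil markers fell in 4 and rose in 2 of 8 (list adjusted p = 0.0526 with no filter) and epithelial markers fell in 3 of 5 (3 fell and 2 rose adjusted over the list alone; list adjusted p = 0.275 with no filter). The neutrophil list had adjusted p = 0.0268, and adjusted p = 0.240 with an estimated correlation. The epithelial list had adjusted p = 0.0321, and adjusted p = 0.290 with an estimated correlation. Checkpoint genes went both ways, with PD-L1, encoded by Cd274, rising in MHC-IIhi (160.2 ± 31.6 to 1579 ± 216 CPM) and MHC-IIlo (143 ± 20.0 to 1423 ± 71.7 CPM). Nos2 rose in MHC-IIhi from 30.9 ± 6.49 to 1551 ± 378 CPM (5.66 ± 0.28) and in MHC-IIlo from 33.6 ± 11.9 to 205 ± 58.9 CPM (2.62 ± 0.25). Arg1 fell in MHC-IIlo from 3870.2 ± 663 to 322 ± 122 CPM (-3.58 ± 0.28, adjusted p = 6.3e-10) and was at -0.34 ± 0.26 in MHC-IIhi (adjusted p = 0.253).

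The last comparison asks which culture changes differed between the subsets. Il1b had a lower culture change in MHC-IIlo than in MHC-IIhi (log2 difference -4.47 ± 0.48, adjusted p = 2.3e-06), as had Cxcl3 (-4.64 ± 0.43, adjusted p = 4.8e-07) and the cytokine Il6 (-7.30 ± 0.58, adjusted p = 6.7e-08). Arg1 (ENSMUSG00000019987, chromosome 10, 24915208 to 24927470) had a difference of -3.24 ± 0.37 (adjusted p = 4.9e-06), Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) one of -3.04 ± 0.34 (adjusted p = 3.2e-06) and Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032377) one of -1.77 ± 0.44 (adjusted p = 0.00827). Among abundant genes positive differences were largest for Egr2 (2.25) and Lpl (2.08, adjusted p = 0.0683 with all 30 libraries in the fit), and negative ones for Ccr7 (-4.79) and Ccl22 (-4.64) besides Il1b and Cxcl3. Without no-lactate MHC-IIlo 3 Ccr7 had -6.55 and Ccl22 -5.40, and H2-Ab1 turned to -0.10. Of 13682 genes 1957 passed, 825 with a higher and 1132 with a lower change in MHC-IIlo, against 1211 and 988 in the FPKM table. H2-Ab1 (0.53 ± 0.47) and Ldhb (-0.21 ± 0.58) did not pass, nor did Mrc1 (0.02 ± 0.23), which passed in the FPKM table (1.05, adjusted p = 0.00169), or Cd74 (-0.51 ± 0.42), which passed without no-lactate MHC-IIlo 3 (-1.05, adjusted p = 0.0185).

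Of 31 lists 19 had a culture change that differed between the subsets, and each call was lost with an estimated correlation. Inflammatory mediators had lower changes in MHC-IIlo (14 lower of 24, 17 lower adjusted over the list alone). The inflammatory mediator list had adjusted p = 5.0e-16, and adjusted p = 0.0855 with an estimated correlation. Hypoxia genes such as Bnip3 at -2.66 and Ddit4 at -2.79 were lower too (1 higher and 17 lower of 20, 2 higher and 18 lower adjusted over the list alone). The hypoxia list had adjusted p = 3.1e-16, and adjusted p = 0.102 with an estimated correlation. Glycolysis genes such as Pfkfb3 at -2.10 went the same way (13 lower of 19, 15 lower adjusted over the list alone). The glycolysis list had adjusted p = 2.8e-10, and adjusted p = 0.102 with an estimated correlation. Checkpoint genes had lower changes (9 lower of 17, 1 higher and 10 lower adjusted over the list alone). The checkpoint list had adjusted p = 5.7e-08, and adjusted p = 0.0855 with an estimated correlation. Alternative activation genes had lower changes (1 higher and 6 lower of 18, 1 higher and 7 lower adjusted over the list alone), as had interferon-stimulated genes (7 lower of 31, 8 lower adjusted over the list alone). The alternative activation list had adjusted p = 3.2e-05, and adjusted p = 0.102 with an estimated correlation. The interferon list had adjusted p = 4.4e-04, and adjusted p = 0.490 with an estimated correlation. Arginine and polyamine genes moved lower (1 higher and 5 lower of 17), though their median turned positive with FPKM (0.01). The arginine and polyamine list had adjusted p = 0.00166, and adjusted p = 0.102 with an estimated correlation. Mitochondrially encoded genes moved lower as well (3 lower of 7, 6 lower adjusted over the list alone). The mitochondrially encoded list had adjusted p = 4.6e-04, and adjusted p = 0.184 with an estimated correlation. NRF2 targets were lower in their change (3 lower of 16), and so were matrix remodelling genes (1 higher and 9 lower of 17, 1 higher and 10 lower adjusted over the list alone). The NRF2 target list had adjusted p = 0.00603, and adjusted p = 0.462 with an estimated correlation. The matrix remodelling list had adjusted p = 3.5e-04, and adjusted p = 0.161 with an estimated correlation. Dendritic cell markers (1 higher and 6 lower of 10, 1 higher and 7 lower adjusted over the list alone) and monocyte markers (4 lower of 8) had lower changes in MHC-IIlo. The dendritic cell list had adjusted p = 0.00155, and adjusted p = 0.176 with an estimated correlation. The monocyte list had adjusted p = 0.00282, and adjusted p = 0.176 with an estimated correlation. Neutrophil (3 lower of 8), fibroblast (7 lower of 9) and endothelial markers (2 lower of 4, 1 higher and 3 lower adjusted over the list alone) followed. The neutrophil list had adjusted p = 0.00406, and adjusted p = 0.102 with an estimated correlation. The fibroblast list had adjusted p = 5.2e-04, and adjusted p = 0.216 with an estimated correlation. The endothelial list had adjusted p = 0.0172, and adjusted p = 0.102 with an estimated correlation. Higher changes in MHC-IIlo were found for MHC class II genes such as H2-DMb1 at 1.65 (4 higher of 13, 5 higher adjusted over the list alone). The MHC class II list had adjusted p = 0.00603, and adjusted p = 0.454 with an estimated correlation. MHC class II genes lost their call at adjusted p = 0.0827 without no-lactate MHC-IIlo 3. The TCA cycle was higher too (6 higher and 1 lower of 23). The TCA cycle list had adjusted p = 0.00436, and adjusted p = 0.176 with an estimated correlation. Nuclear oxidative phosphorylation (5 higher of 58, 1 higher adjusted over the list alone) and cholesterol genes (2 higher of 23, 7 higher and 1 lower adjusted over the list alone) likewise had higher changes. The nuclear oxidative phosphorylation list had adjusted p = 0.00320, and adjusted p = 0.587 with an estimated correlation. The cholesterol list had adjusted p = 0.00603, and adjusted p = 0.462 with an estimated correlation.

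**Figure D4:**
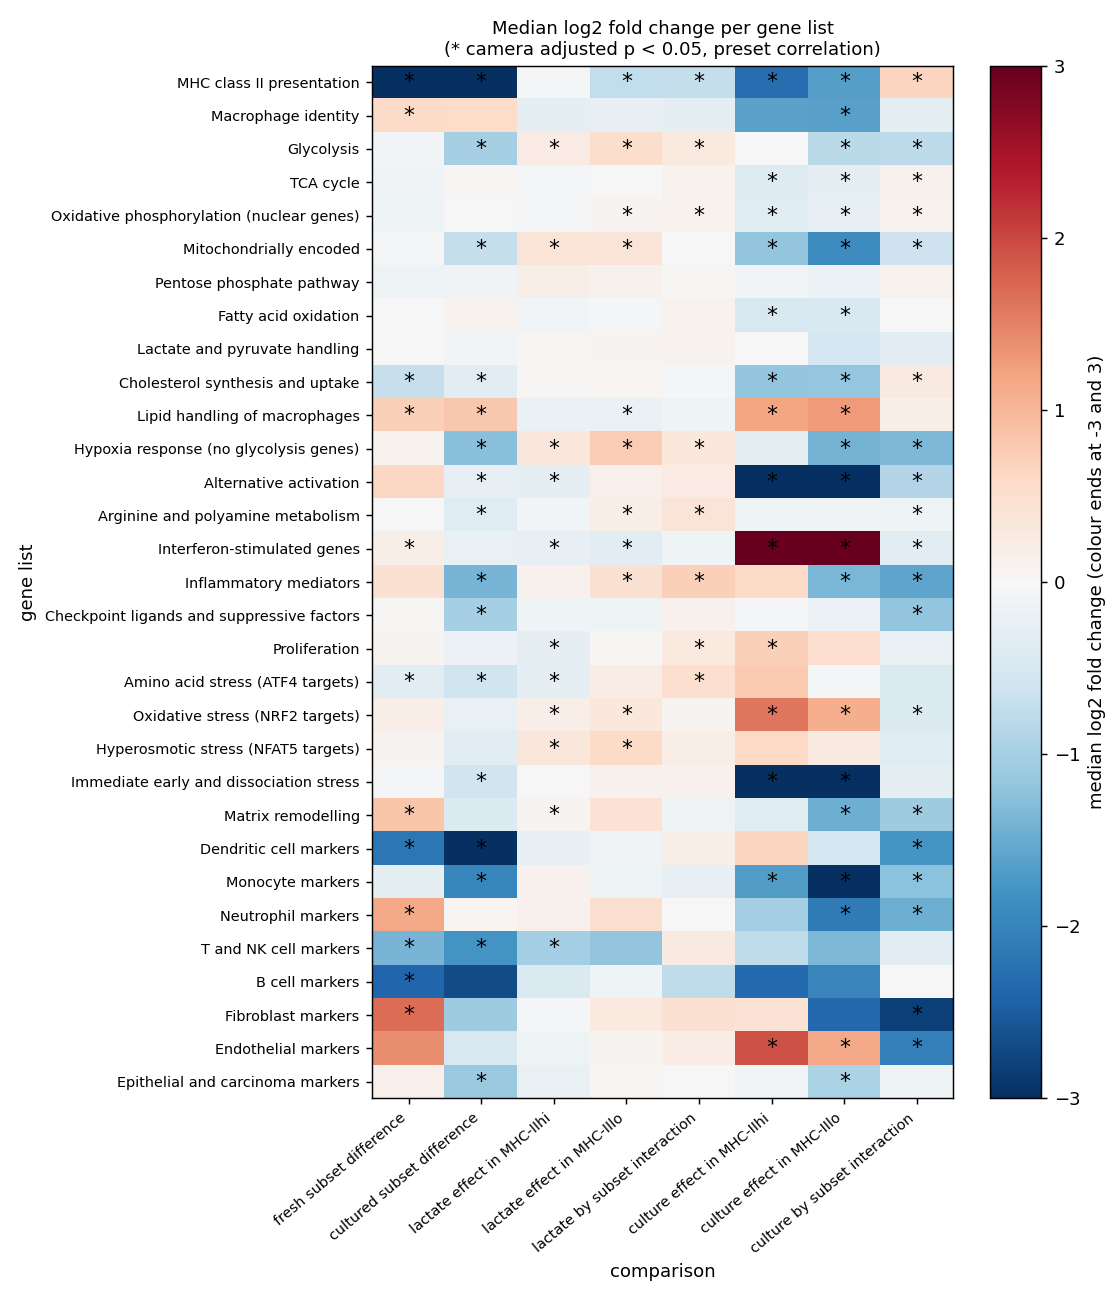
The heat map gives the median log2 fold change of each of the 31 gene lists (y axis) in each of the 8 comparisons (x axis), red for positive and blue for negative values, and a star marks a list past the camera test with its preset correlation. The interferon list was high with culture in both subsets (4.17 and 3.74), and the MHC class II list was low in MHC-IIlo in fresh (-4.13) and cultured cells (-4.20).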

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

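The tests on dendritic cell, neutrophil, fibroblast, hypoxia, glycolysis and MHC class II genes were chosen after the results were seen, and the counts over other splits were planned. Some libraries stood far from the other 4 of their group by Dixon's ratio of the gap to the range, which chance alone gives in about 1 in 20 groups. H2-Ab1 was at 71.6 CPM and Cd74 at 222 CPM in no-lactate MHC-IIlo 3, above the rest of that group, and Il1b was at 733 CPM in lactate MHC-IIhi 6. In lactate MHC-IIlo 5 Il1b was at 129 CPM, the TMM factor was 1.28, ribosomal protein genes took 1.67% of counts and the 10 most abundant genes 7.16%. Of 189 other named genes, 1 library stood far from the rest for 10 in fresh MHC-IIhi (4 of them in library 3), 10 in fresh MHC-IIlo (3 of them in library 1), 5 in no-lactate MHC-IIhi (2 of them in library 5), 28 in no-lactate MHC-IIlo (19 of them in library 3), 12 in lactate MHC-IIhi (5 of them in library 1) and 32 in lactate MHC-IIlo (22 of them in library 5).

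Effects that differed between the subsets by a test of the difference were the culture change of 1957 genes, among them Il1b (-4.47), Arg1 (-3.24), Nos2 (-3.04) and Vegfa (-1.77), the culture change of 19 lists and the lactate change of 8 lists. With an estimated correlation camera called 0 of either, with adjusted p of at least 0.0855 and 0.842, and 9 and 1 of 31 lists under an unadjusted p of 0.05.

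Dendritic cell markers were higher in MHC-IIhi than MHC-IIlo in 7 of 10 in fresh cells (adjusted p = 0.385 with an estimated correlation) and 9 of 9 in cultured cells (adjusted p = 0.00654 with an estimated correlation): Flt3 was at 2.19 ± 0.914 CPM in fresh and 29.1 ± 13.5 CPM in cultured MHC-IIhi, and Ccr7 at 5.07 ± 2.95 and 146 ± 63.7 CPM. A fixed share of dendritic cells with unchanged expression is argued against by the 7 of 10 markers whose culture change differed between the subsets (6 lower and 1 higher in MHC-IIlo). A lower share of macrophages in MHC-IIhi stays open, as macrophage identity genes went both ways. Adjusted over the list alone 3 were higher in cultured MHC-IIhi (Csf1r, Itgam and Cd14), with Cd68, C1qa and C1qc among the lower ones. Dendritic cells that outlived other cells or matured in culture stay open as a candidate source, with Flt3 and Zbtb46 higher in MHC-IIhi in 4 of 4 tests (2 genes, fresh and cultured). A change of the macrophages themselves stays open too. Of the 12 listed genes 4 were at 1 CPM or more in both cultured subsets, but bulk libraries cannot tell which cells those reads came from. The sort for MHC class II would not remove dendritic cells by itself, and what other gates were set was not analysed here.

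Neutrophil markers were higher in 7 of 8 and fibroblast markers in 5 of 9 in fresh MHC-IIlo (adjusted p = 0.385 and 0.633 with an estimated correlation). Neutrophils as the source of the Mmp8 and Mmp9 difference (257 and 502 CPM) are argued against by S100a8 and S100a9, their most abundant transcripts, which differed by 7.88 and 14.5 CPM, a ratio of 0.0295. Fibroblast RNA in the MHC-IIlo sort stays open as a candidate source: Col1a1, Col3a1 and Col1a2, the most abundant transcripts of that list, differed by 20.8, 12.8 and 9.87 CPM, and 0 of the other members differed by more than the median of these 3, the nearest being Col6a1 at 5.87 CPM. Of the listed genes, 6 of 12 neutrophil and 8 of 10 fibroblast markers were at 1 CPM or more in both fresh subsets, and 2 neutrophil markers are also in the matrix list. A biological difference in matrix genes of the macrophages was not tested.

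With lactate in MHC-IIlo the hypoxia and glycolysis lists moved up and the MHC class II list moved down, though not with an estimated correlation (adjusted p = 0.361, 0.275 and 0.519 with an estimated correlation). That lactate MHC-IIlo 5 alone made the first is argued against by the lists without it (the larger adjusted p was 2.5e-10). For the MHC class II list the mean log2 fold change went from -0.81 (SD 0.94 over genes) to -0.61 (SD 0.95) without it. Its adjusted p was then 0.0794 (2.2e-04 to 0.519 over all alternatives), and 0.0371 with the header block as well, with a smaller mean and 4 libraries left, so how much of the fall that library made stays open. Without no-lactate MHC-IIlo 3, the library high in H2-Ab1 and Cd74, that list had adjusted p = 0.0302. A shift of MHC-IIlo libraries toward the MHC-IIhi state stays open. Hypoxia and glycolysis moved that way, while 0 of 13 MHC class II genes rose (3 fell, adjusted over the list alone). The sodium salt and the osmolality cannot be told apart from lactate, since no group got another salt, and the NFAT5 list, which high osmolality raises, moved up as well (adjusted p = 4.6e-05, and adjusted p = 0.0670 with an estimated correlation). A difference in library quality was not tested and stays open too, as each lactate MHC-IIlo library had more ribosomal RNA than any no-lactate MHC-IIlo library. So does an effect of lactate itself.

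Other splits of the same libraries were counted, 100 per comparison with the real one. Chance can be excluded for the cultured subsets (1 of 100 splits gave 2830 genes or more, highest other 55). So it can for culture in MHC-IIhi (1, 8484 and 2288) and MHC-IIlo (1, 7867 and 1007). In the fresh comparison the 15 other splits that part all 5 pairs gave at most 0 genes by edgeR, and the 567 came from a split that parts 1 pair. Chance can also be excluded for lactate in MHC-IIhi (2, 34 and 753) and in MHC-IIlo (2, 202 and 467). For the culture difference between subsets (2, 1957 and 2445) it cannot, as the splits also broke up the culture change itself. The lactate splits took no account of header numbers, though in MHC-IIlo the same number was the best partner in 4 of 5 (0.0646 to 0.515), so they did not test a shared source of those libraries. For the lactate difference between subsets edgeR called 0 genes (1018 under an unadjusted p of 0.05, 2 with DESeq2 and 2 with limma voom), which each of the 100 splits reaches by design (highest other 1), so the splits say nothing about chance there. The split with 753 genes calls many times the real count and points to a structure of the samples: it set no-lactate MHC-IIhi 5 and 6 with lactate MHC-IIhi 1, 3 and 5. The split with 467 genes also points to one, as it exchanged no-lactate MHC-IIlo 4 and lactate MHC-IIlo 1. That with 2445 genes had 8 of 10 cultured libraries on 1 side.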

How the results depend on the processing

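The block on the header number and the fits without lactate MHC-IIlo 5 were tests chosen after the data were seen. Gene counts of the fresh subsets (3221 to 3667 with 1 library left out), culture in MHC-IIhi (8127 to 8395), culture in MHC-IIlo (7440 to 7844) and the culture difference between subsets (1645 to 2058) stayed within 1.5 times the reported ones under each alternative, and that of the cultured subsets (2205 to 2643) did except with limma voom (4335). With 1 library left out lactate gave 8 to 27 genes in MHC-IIhi and 53 to 758 in MHC-IIlo. Respective counts were 131 and 689 with DESeq2, 53 and 531 with all 30 libraries, 81 and 1111 with the header block and 255 and 631 with that block and without lactate MHC-IIlo 5, besides 54 in MHC-IIhi without that library and 1502 in MHC-IIlo with limma voom. The lactate difference between subsets, 0 genes by edgeR with 1018 under an unadjusted p of 0.05, 2 with DESeq2 and 2 with limma voom, gave 0 to 8 with 1 library left out (8 without lactate MHC-IIlo 1 and 1 without no-lactate MHC-IIhi 7), 1 with all 30 libraries, 2 with the header block and 2 with lactate MHC-IIlo 5 out as well. Leaving out a library lowers the number of samples; for the other moves the cause was not tested.

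With the correlation between genes estimated from the data, the lists past the threshold numbered 1 in place of 12 for the fresh subsets, 5 of 16 for the cultured subsets, 1 of 14 for culture in MHC-IIhi and 3 of 20 for culture in MHC-IIlo. For lactate in MHC-IIhi (11 lists), lactate in MHC-IIlo (11), the lactate difference (8) and the culture difference (19) the number by camera fell to 0, with 2, 4, 1 and 9 of 31 lists under an unadjusted p of 0.05. Lists without a call passed in places, as proliferation with culture in MHC-IIlo (adjusted p = 0.00242 to 0.761 over alternatives), macrophage identity (0.00591 to 0.607) and lactate handling (0.0219 to 0.176) in the culture difference, and TCA cycle (0.00694 to 0.842) and macrophage identity (0.00944 to 0.842) in the lactate difference. With no filter 19 lists passed for the fresh subsets, where more genes are tested. The interferon list of the lactate difference changed direction with the header block and without lactate MHC-IIlo 5 (adjusted p = 0.00988, 0.00103 to 0.907 over all alternatives), and the cause was not tested.

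Of 368 named results for single genes, 2 lost their call with RLE size factors, 3 with no filter, 3 with limma voom and 13 with all 30 libraries, and of 355 with FPKM values 8 did with a pseudocount of 1 and 9 with 0.1. Of 4330 such results with 1 library left out 82 lost and 4 gained a call, and no gene that passed as reported changed direction. Genes that had not passed did in places, as Ldhb with lactate in MHC-IIhi (0.47 ± 0.56, and -0.28 with the header block). The planned block on the labels' replicate number was not run for the cultured comparisons, since their columns carry other numbers than the labels. By the rule of a correlation over 0.1 in each same-number pair, header numbers pair no 2 cultured groups that are compared directly. It was 0.0646 to 0.515 between no-lactate and lactate MHC-IIlo, with the same number the best partner in 4 of 5, -0.528 to 0.653 (2 of 4) in MHC-IIhi, -0.0958 to 0.471 (2 of 4) between no-lactate and -0.166 to 0.656 (4 of 5) between lactate subsets. Of the cross pairs, no-lactate MHC-IIhi with lactate MHC-IIlo met the rule at 0.172 to 0.420 (2 of 4), and no-lactate MHC-IIlo with lactate MHC-IIhi did not at -0.173 to 0.508 (2 of 5). Simulated recovery of 1.5-fold changes was 53.7% in fresh subsets, 26.9% for lactate in MHC-IIhi, 35.8% in MHC-IIlo and 5.97% for the lactate difference.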

Other observations

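The test below was planned after lactate MHC-IIlo 5 was seen to stand apart and before its own result was seen. If MHC-IIhi and MHC-IIlo share a lactate response, an average over both subsets without that library would call more genes than either subset alone. It called 476 genes, against 133 in MHC-IIlo and 54 in MHC-IIhi, so a common response may underlie part of the changes, among them those of Slc6a12, Olfml2b and Slc16a6. An average also has more libraries than either subset, which raises the count by itself, and the test does not part lactate from its sodium salt.

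These members of marker lists were singled out after their culture values were seen. Kdr was at 3.45 ± 0.934 CPM in fresh and 384 ± 134 CPM in cultured MHC-IIhi, and at 8.81 ± 1.53 and 302 ± 39.9 CPM in MHC-IIlo. Vwf was at 6.49 ± 1.24 and 32.2 ± 16.5 CPM in MHC-IIhi and 4.54 ± 0.541 and 41.8 ± 5.102 CPM in MHC-IIlo, and the B cell factor Pax5 at 6.36 ± 2.24 and 37.6 ± 11.2 CPM in MHC-IIhi and 5.96 ± 3.34 and 29.7 ± 6.63 CPM in MHC-IIlo. Over the same step the B cell marker Ighm went from 8.34 ± 2.16 to 1.80 ± 0.615 CPM in MHC-IIhi and the endothelial marker Cdh5 from 11.97 ± 6.32 to 6.23 ± 0.916 CPM in MHC-IIlo.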
